A study of Sus scrofa with 4 samples.

How the data were processed

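RNA was sequenced from follicle granulosa cells of the pig (Sus scrofa), the somatic cells that surround the oocyte in the ovarian follicle. The 4 libraries fall into 2 groups of 2, a transfection negative control and a group transfected to interfere with YTHDF2, written siYTHDF2 here. The group of each library was taken from its treatment label and its replicate number from its title. The labels name no BDNF treatment, no siRNA sequence and no separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

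Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit. The same protocol text speaks of retinas, and the submitters' processing notes name Bowtie 0.12.2 and a mouse genome build. Neither fits a pig granulosa cell series, and the gene identifiers in the deposited table are those of the pig, so the aligner, build and annotation behind the values are treated as not given in the sources used here. Of 12761 gene symbols shared with a table of the Sscrofa11.1 assembly, 89.3% started within 5000 bases of the same position on the same chromosome. Coordinates are printed as the deposited table gives them.

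The authors deposited 1 table of 20491 genes with counts per library and FPKM values per library, next to gene positions, names, GO terms and KEGG pathways. Per the file headers the count columns hold counts and the FPKM columns FPKM. How reads were counted, and whether strand was used, is not given in the sources used here. For the 12083 genes with at least 50 counts in every library, the scaled ratio of count to FPKM differed between libraries by at most 4.33%, so both units carry the same measurement. The deposited counts do not behave like plain read counts at the low end. In transfection control replicate 1, 682 genes had a count of 4, against 274 genes at 3 and 145 genes at 5. Zeros were also more frequent than counting error gives: among genes with a mean of 10 to 20 counts in the other 3 libraries, 9.98% to 15.3% were listed at 0 in the remaining library. Genes listed at 0 in both libraries of a group are therefore given with their counts and with no fold change. Symbols came from the table, and 124 of the 6435 identifiers without a symbol there were named through the reference table of genes. GO terms of 1364 genes were not used here.

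The total count was 53331003 and 54841851 in the control libraries and 47209177 and 54203550 in the siYTHDF2 libraries. The most abundant gene, THBS1, took between 2.13% and 2.83% of a library's counts. Each library was counted as its own sample. The chi-square per degree of freedom between replicates was 17.4 in the control pair and 17.1 in the siYTHDF2 pair, which takes each count as an independent fragment and is inflated if fragments were counted several times.

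Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, using its expression filter, TMM scaling and the two-sided quasi-likelihood test with robust shrinkage and group as the only term. The design fixed before the data were examined named limma on log2(FPKM + 1) unless the table also held counts, in which case this test took its place, and it did. P-values were adjusted by Benjamini-Hochberg over the 15552 genes tested, with a threshold of 0.05. Values per group are TMM-scaled CPM (counts scaled to a common library size) as mean ± SD. The 35 gene lists, among them markers of 7 cell types, were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset between-gene correlation of 0.01, adjusted over the 33 lists with at least 5 tested members. An estimated correlation and the fry test were run beside it. GO terms and KEGG pathways of 10 to 500 genes were tested among called genes with a one-sided hypergeometric test. The background was the tested genes that carry a term of that source. The hypergeometric test takes genes as independent draws, so its p-values do not measure the spread between libraries.

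The genes named are drawn by a rule fixed in advance. It takes YTHDF2, BDNF, NTRK2, NGFR, CCND1, CCND2, PCNA and MKI67 whatever their result, the 12 largest changes per direction among called genes with a symbol and non-overlapping groups, and up to 4 members with the smallest p per described list. MKI67 was not analysed here. NTRK2 had counts of 0 and 0 in the control and 0 and 6 in the siYTHDF2 libraries and was too low to test. Mitochondrially encoded transcripts were not analysed here. Genes said to be chosen after their values were seen stand outside the rule.

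The test was tried on simulated counts for 15552 genes with the libraries' means and sizes. It recovered 55.2% of genes changed by 1.5-fold, 65.7% at 2-fold and 84.8% at 4-fold, with 8 false calls among 14971 unchanged genes. With each fragment counted 4 times, it recovered 43.3%, 71.6% and 81.8%, with 2 false calls among 14901. The simulated genes were drawn independently, without the excess zeros of the deposited counts or shifts of whole libraries. These rates therefore need not hold for the deposited counts. Alternatives tried were other filters, scalings and spread models, the replicate number as a block, leaving out each library and other list tests. On FPKM, limma was tried with pseudocounts of 0.1 and 0.5, and after quantile normalization of log2(FPKM + 1). Against the edgeR test, quantile normalization was thus tried only together with a change of test, unit and filter. Against limma on log2(FPKM + 1) it was the only change. Added as alternatives after seeing the data were limma with a pseudocount of 1 and a mean FPKM of at least 1, and DESeq2 1.42.0. That limma test itself was the one named in advance for a table without counts. Counts divided by 4 and the edgeR test with a mean FPKM of at least 1 were also chosen then.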

Results

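Gene expression was measured by RNA sequencing in pig granulosa cells after interference with YTHDF2, a reader protein that binds N6-methyladenosine (m6A) in mRNA and promotes decay of bound transcripts. The series concerns whether YTHDF2 mediates the stimulation of granulosa cell proliferation by BDNF, a neurotrophin. The comparison was between 2 siYTHDF2 libraries and 2 transfection control libraries, with total counts of 47209177 to 54841851 per library.

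YTHDF2 itself was lower in both siYTHDF2 libraries. Its CPM was 65.8 ± 5.23 in the control and 23.4 ± 0.270 with siYTHDF2 (SD, n = 2 each), a log2 fold change of -1.49 (SE 0.09, adjusted p = 1.49e-05). The deposited counts of YTHDF2 were 3660 and 3356 in the control libraries and 1122 and 1279 in the siYTHDF2 libraries. The gene, ENSSSCG00000027686, lies on chromosome 6 from 85716983 to 85726473 in the deposited table.

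Interference with YTHDF2 was accompanied by lower transcripts of the extracellular matrix and of stromal markers and by higher transcripts of G2 and M phase genes, as lists tested with camera at a preset correlation. Each of these 3 list calls was lost with an estimated correlation (adjusted p = 0.447), and the G2 and M phase call also with fry (adjusted p = 0.0525). With 2 libraries per group no list passed with an estimated correlation. The smallest unadjusted camera p there was 0.0136, for the stroma list, although its estimated correlation of -0.0245 lay below the preset 0.01. A call lost there therefore need not reflect correlated genes. The matrix and stroma lists share 4 tested genes. COL3A1, which encodes a fibrillar collagen, fell from 1245 ± 25.7 to 353 ± 6.43 CPM, and CCND1, which encodes cyclin D1, rose from 66.5 ± 0.404 to 173 ± 4.30 CPM (SD, n = 2 each). Of 15552 genes tested, 1408 were higher and 1644 lower with siYTHDF2 at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Most of these changes were small, since 124 of the higher and 328 of the lower genes changed by at least 2-fold.

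The number of higher genes depended on single libraries, and in limma on quantile normalization (1365 higher and 1454 lower with it). It was 879 without transfection control replicate 1 and 791 without siYTHDF2 replicate 1, while limma on log2(FPKM + 1) called 445 higher and 1211 lower genes.

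**Figure D1:**
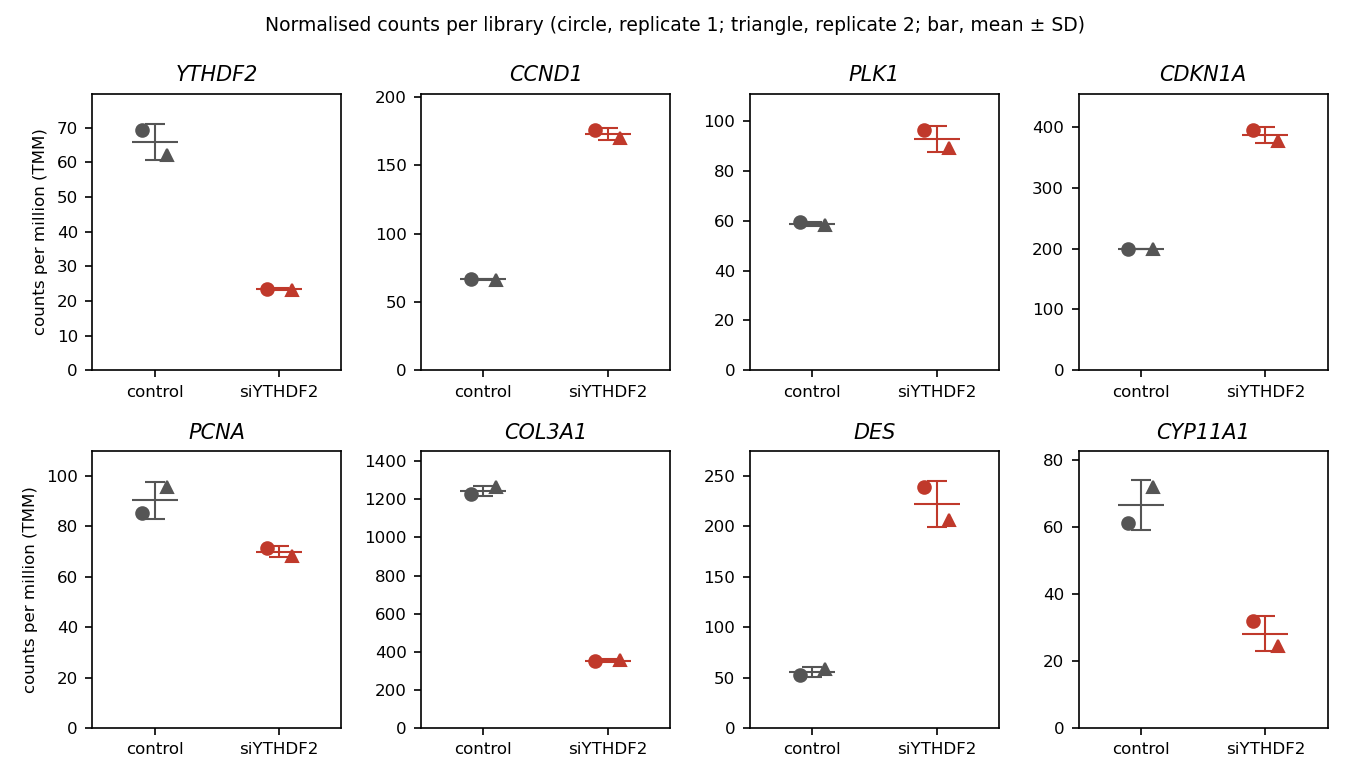
TMM-scaled CPM (linear axes from 0) of 8 genes in the 2 control (grey) and 2 siYTHDF2 (red) libraries, with group means and SD as bars. YTHDF2, PCNA, COL3A1 and CYP11A1 were lower and CCND1, PLK1, CDKN1A and DES higher in both siYTHDF2 libraries than in both controls.

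Among the genes that the comparison was set up to follow, CCND1 had a log2 fold change of 1.38 (SE 0.07, adjusted p = 6.91e-06). CCND2, which encodes cyclin D2, was higher by 0.39 on the log2 scale (SE 0.11, adjusted p = 0.0386), and PCNA, the sliding clamp of DNA replication, had a log2 fold change of -0.37 (SE 0.08, adjusted p = 0.0123). The CCND2 call was lost without transfection control replicate 1 (adjusted p = 0.175) and without siYTHDF2 replicate 1 (adjusted p = 0.161), in limma on log2(FPKM + 1) (adjusted p = 0.232), with the replicate number as a block (adjusted p = 0.0638) and without trend and robust shrinkage (adjusted p = 0.0538). The PCNA call was lost without transfection control replicate 2 (adjusted p = 0.0519). BDNF stood at 88.7 ± 3.46 CPM in the control and 86.8 ± 2.34 CPM with siYTHDF2 (SD, n = 2 each), a difference within the spread between replicates (log2 fold change -0.03, SE 0.07, adjusted p = 0.816). NGFR, which encodes the p75 neurotrophin receptor, was listed at 0 in both control libraries and had counts of 42 and 32 in the siYTHDF2 libraries. FRS2, an adaptor of receptor tyrosine kinases, fell by 0.94 on the log2 scale (SE 0.17, adjusted p = 0.00517). The neurotrophin list holds ligands and receptors and also signalling proteins such as FRS2. Of its 11 tested members 1, NGFR, was higher and 3 were lower (1 and 4 adjusted over the list alone). The list was not past the threshold (camera adjusted p = 0.302).

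Part of the G2 and M phase genes rose. Of 33 tested members 16 were higher, none lower and 17 not called (18 and 1 adjusted over the list alone), and the list passed the test (camera adjusted p = 8.59e-07). The call was lost with an estimated correlation (adjusted p = 0.447) and with fry (adjusted p = 0.0525). PLK1, a mitotic kinase, rose by 0.66 on the log2 scale (SE 0.07, adjusted p = 0.000462), and UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, by 0.59 (SE 0.10, adjusted p = 0.00394). CKS1B and CKS2, which bind cyclin-dependent kinases, were higher by 0.66 and 0.51. In contrast, the 34 G1 and S phase genes had 4 higher and 5 lower members, also when adjusted over the list alone, with a camera adjusted p = 0.793. UHRF1, which maintains DNA methylation at replication, fell by 0.48 on the log2 scale (SE 0.08, adjusted p = 0.00406).

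Cell cycle inhibitors moved in both directions. CDKN1A, which encodes p21, rose from 199.7 ± 0.35 to 387 ± 13.1 CPM (SD, n = 2 each, adjusted p = 2.34e-05), whereas CDKN2B, which encodes p15, fell from 34.9 ± 0.769 to 15.1 ± 0.416 CPM (SD, n = 2 each, adjusted p = 8.45e-05). GADD45B, a stress-response gene, fell by 1.06 on the log2 scale (SE 0.11, adjusted p = 0.000349). Of the 14 inhibitors 1 was higher and 3 lower, also over the list alone (camera adjusted p = 0.716). The 23 p53 target genes, a list that also holds CDKN1A, had 9 higher and 2 lower members (10 and 3 adjusted over the list alone; camera adjusted p = 0.0119, and adjusted p = 0.447 with an estimated correlation). MDM2, the ubiquitin ligase of p53, rose by 0.57 (SE 0.07, adjusted p = 0.000971), while SESN1, a stress-induced regulator of mTORC1, fell by 0.53 (SE 0.13, adjusted p = 0.0179). The SESN1 call was lost without siYTHDF2 replicate 1 (log2 fold change -0.44). The call of the p53 list was lost in limma on log2(FPKM + 1) (adjusted p = 0.0630), also with quantile normalization added to it (adjusted p = 0.0624).

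Extracellular matrix genes fell as a list. Of 39 tested members 28 were lower and 4 higher (30 and 5 adjusted over the list alone), with a median log2 fold change of -0.53 (camera adjusted p = 6.46e-26, and adjusted p = 0.447 with an estimated correlation). FN1, which encodes fibronectin, fell from 7429 ± 244 to 2913 ± 219 CPM, and COL1A1, the main fibrillar collagen chain, from 3085 ± 236 to 1202 ± 83.2 CPM (SD, n = 2 each). THBS2, a matricellular glycoprotein, had a log2 fold change of -1.84 (SE 0.11, adjusted p = 1.42e-05). Annotation terms were tested on the same calls, so they are not independent of this list. In GO, 48 of 132 extracellular matrix genes were among the lower genes against 14.6 expected (hypergeometric adjusted p = 1.47e-11). Of the 72 genes in the KEGG pathway ECM-receptor interaction 32 were lower (adjusted p = 1.60e-08).

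Markers of theca and ovarian stroma, the cell types next to the granulosa layer, moved with these genes, and 4 of the 15 tested stroma markers are also on the matrix list. These 4, COL1A1, COL3A1, DCN and LUM, were lower in both siYTHDF2 libraries than in both controls. The stroma and matrix results are therefore not independent. Of the 15 markers 8 were lower and 1 higher, also over the list alone (camera adjusted p = 3.39e-14, and adjusted p = 0.447 with an estimated correlation). MYH11, a smooth muscle myosin, fell from 647 ± 33.8 to 289 ± 7.41 CPM, whereas DES, the muscle intermediate filament desmin, rose from 55.4 ± 4.58 to 222 ± 22.9 CPM (SD, n = 2 each). Granulosa cell markers had 3 higher and 1 lower of 21 members (3 and 2 adjusted over the list alone; camera adjusted p = 0.523). Among them SERPINE2, a protease inhibitor, rose by 0.98 (SE 0.06, adjusted p = 2.29e-05) and INHBB, which encodes the inhibin beta B subunit, fell by 0.69 (SE 0.11, adjusted p = 0.00213). Levels of granulosa markers differed widely. In examples chosen after their values were seen, AMH lay at 0.185 to 2.10 CPM, FOXL2 at 4.35 to 6.38 and GJA1 at 2106 to 2515. The stroma marker ACTA2 lay at 6286 to 12801 CPM. The counts of calls therefore do not measure how pure the cells were. Endothelial markers had 1 higher member of 9 (2 adjusted over the list alone), VWF, which was listed at 0 in both control libraries with counts of 24 and 30 in the siYTHDF2 libraries (camera adjusted p = 0.573). The 6 tested leukocyte markers had no call in edgeR (camera adjusted p = 0.716), and 1 of them, CD14, had an unadjusted p under 0.05. Epithelial markers had 1 lower of 6 members (none adjusted over the list alone; camera adjusted p = 0.615). CLDN4 of this list was at 0 in both siYTHDF2 libraries and at only 0.209 and 0.278 CPM in the controls. Only 4 oocyte markers could be tested, too few for a list test, and KIT, a receptor kinase, was the lower one of these at 124 ± 7.88 against 204 ± 6.86 CPM in the control (SD, n = 2 each).

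**Figure D2:**
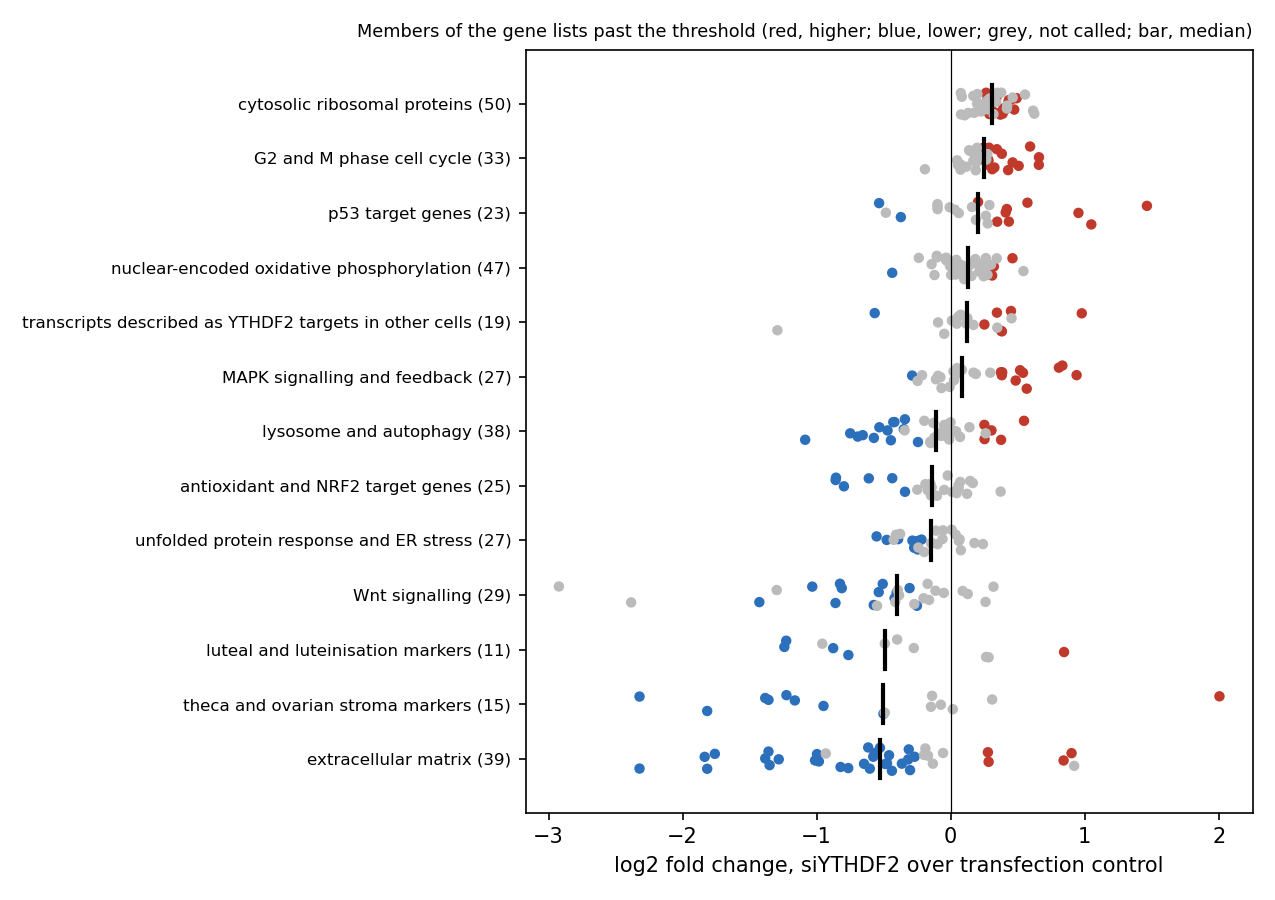
Log2 fold changes (x axis, siYTHDF2 over transfection control) of the tested members of the 13 gene lists past the threshold, with the number tested in brackets; red, blue and grey points are higher, lower and uncalled genes, and black bars list medians. Extracellular matrix genes had a median of -0.53 and ribosomal protein genes of 0.31.

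Luteal markers fell as a list, which shares 3 genes with the steroidogenesis list. Of 11 luteal markers 4 were lower and 1 higher (4 and 2 adjusted over the list alone; camera adjusted p = 0.0119, and adjusted p = 0.538 with an estimated correlation). CYP11A1, the cholesterol side-chain cleavage enzyme, fell from 66.6 ± 7.55 to 28.2 ± 5.34 CPM, and OXTR, the oxytocin receptor, from 55.9 ± 5.47 to 23.9 ± 1.29 CPM (SD, n = 2 each). VEGFA, which encodes an angiogenic growth factor, was the member that rose, by 0.85 on the log2 scale (SE 0.08, adjusted p = 0.000138). The 17 steroidogenesis genes had 2 lower members, CYP11A1 and the lipoprotein receptor SCARB1 at -0.76 (SE 0.07, adjusted p = 9.75e-05), the same count over the list alone (camera adjusted p = 0.336, and adjusted p = 0.0389, lower, with fry). The luteal list was not past the threshold in limma on quantile-normalized log2(FPKM + 1) (adjusted p = 0.181) or with fry (adjusted p = 0.0615).

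Part of the Wnt signalling genes fell. Of 29 tested members 12 were lower, none higher and 17 not called (14 and 0 adjusted over the list alone; camera adjusted p = 3.97e-06, adjusted p = 0.447 with an estimated correlation and 0.0525 with fry). The secreted Wnt antagonists SFRP1 and SFRP4 had log2 fold changes of -1.43 (SE 0.15) and -1.03 (SE 0.12), and TCF7, a transcription factor of the pathway, -0.86 (SE 0.10). The MAPK list moved the other way, with 10 higher and 1 lower of 27 members (11 and 2 adjusted over the list alone; camera adjusted p = 0.00209, and adjusted p = 0.447 with an estimated correlation). DUSP5, a phosphatase that inactivates ERK, rose by 0.94 on the log2 scale (SE 0.08), and SPRY4, an inhibitor of receptor tyrosine kinase signalling, by 0.83 (SE 0.12). The PI3K, AKT and FOXO list had 7 lower and no higher of 28 members (8 and 2 adjusted over the list alone; camera adjusted p = 0.0949), including the transcription factor FOXO1 at -0.68 (SE 0.07, adjusted p = 0.000237).

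Lysosome and autophagy genes were lower as a list, with 13 lower and 5 higher of 38, also over the list alone (camera adjusted p = 0.00972, and adjusted p = 0.491 with an estimated correlation). CTSL, a lysosomal protease, fell by 1.09 on the log2 scale (SE 0.11), and NPC1, which exports cholesterol from lysosomes, fell by 0.69 (SE 0.08). In the KEGG lysosome pathway 36 of 112 genes were lower (hypergeometric adjusted p = 1.81e-05). Some of its members were called higher, among them CLTB at 0.59 and AP1S1 at 0.48, chosen after their values were seen. The antioxidant list had 6 lower and no higher of 25 members (7 and 1 adjusted over the list alone; camera adjusted p = 0.0119, and adjusted p = 0.670 with an estimated correlation), with GPX3, a secreted glutathione peroxidase, falling from 1085 ± 4.47 to 599 ± 19.7 CPM (SD, n = 2 each). The endoplasmic reticulum stress list had 8 lower and no higher of 27 members (10 and 1 adjusted over the list alone; camera adjusted p = 0.0151, and adjusted p = 0.670 with an estimated correlation), and HERPUD1 of this list fell by 0.55 (SE 0.07). Without transfection control replicate 2 neither list passed (adjusted p = 0.0713 for the antioxidant list and 0.118 for the stress list), nor did the antioxidant list without siYTHDF2 replicate 2 (adjusted p = 0.0658) or either list with fry (adjusted p = 0.0967 for each).

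Ribosomal protein genes were higher by a small amount. All 50 tested members had a positive log2 fold change, with a median of 0.31, and 23 were called higher (33 adjusted over the list alone; camera adjusted p = 1.47e-09). The call was lost with an estimated correlation (adjusted p = 0.708) and with fry (adjusted p = 0.268). RPSA rose by 0.43 on the log2 scale (SE 0.07, adjusted p = 0.00409), and reads of such genes can be shared with their many pseudogenes. Among annotation terms, translation had 68 of 247 genes higher against 24.8 expected (hypergeometric adjusted p = 6.12e-12). The KEGG ribosome pathway had 45 of 125 (hypergeometric adjusted p = 5.54e-11). These p-values take genes as independent draws, whereas the ribosomal protein list had an estimated correlation of 0.91. Both terms were lost without transfection control replicate 1, translation with 18 and ribosome with 8 higher genes (adjusted p = 1 for each). Without siYTHDF2 replicate 1, translation had 23 higher genes (adjusted p = 0.355) and ribosome 12 (adjusted p = 0.681). Without siYTHDF2 replicate 2 the counts went up instead, to 97 for translation and 80 for ribosome (adjusted p = 3.15e-47), and without transfection control replicate 2 they were 70 and 49. Terms enriched among higher genes numbered 67 in all, 5 without transfection control replicate 1 and 11 without siYTHDF2 replicate 1, against 48 terms among lower genes. Oxidative phosphorylation genes had 4 higher and 1 lower of 47 members (0 and 1 adjusted over the list alone; camera adjusted p = 0.0494, and adjusted p = 0.821 with an estimated correlation), and this call was lost in most alternatives, among them without transfection control replicate 1 (adjusted p = 0.410), without siYTHDF2 replicate 1 (adjusted p = 0.488) and with median ratio scaling (adjusted p = 0.0514).

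**Figure D3:**
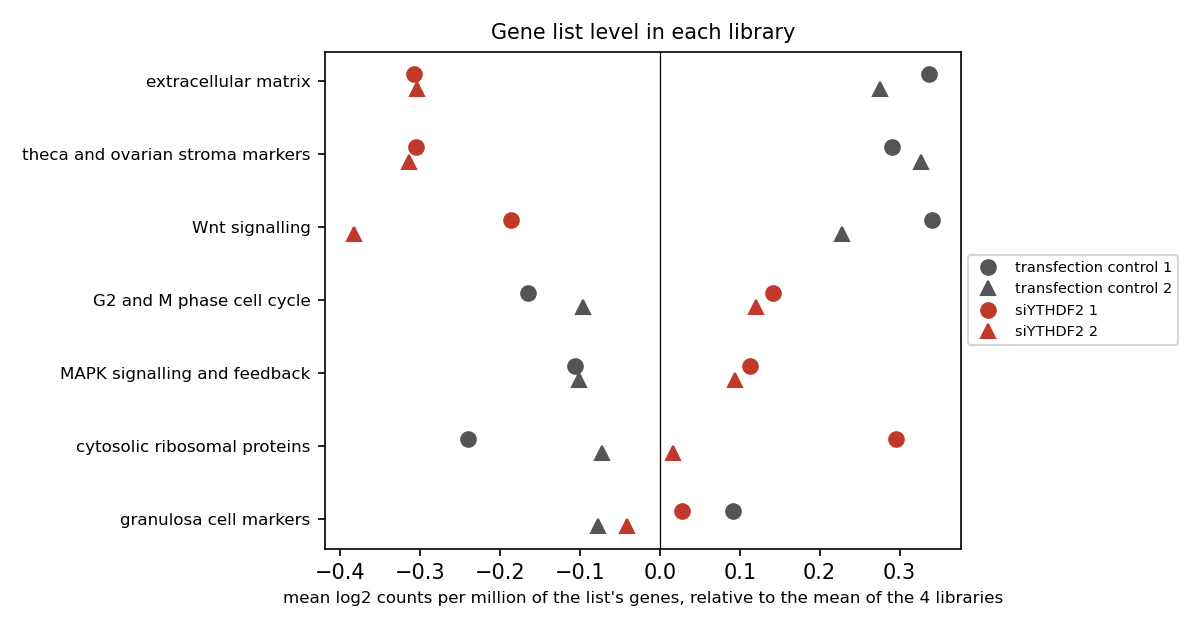
Mean log2 CPM of 7 gene lists in each library, relative to the mean of the 4 libraries (x axis); grey is control, red siYTHDF2, circles are replicates 1 and triangles replicates 2. Matrix genes lay at 0.34 and 0.27 in the controls and -0.31 and -0.30 with siYTHDF2, whereas ribosomal protein genes lay at -0.24 and -0.07 in the controls and 0.30 and 0.02 with siYTHDF2.

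Transcripts described as YTHDF2 targets in other cells had 6 higher and 1 lower of 19 members (7 and 1 adjusted over the list alone; camera adjusted p = 0.0163, and adjusted p = 0.605 with an estimated correlation). SERPINE2 had the smallest p of these, and EGFR, the epidermal growth factor receptor, was the lower member at -0.57 (SE 0.09, adjusted p = 0.00286). The list call was lost without transfection control replicate 2 (list mean 0.04). It was also lost in limma on log2(FPKM + 1) (adjusted p = 0.0692), there with quantile normalization added (adjusted p = 0.0554), and with fry (adjusted p = 0.0967). With no filter on low values the list mean of 0.11 turned to -0.11. In that setting the list has a further member too low to test otherwise, and the list still passed (adjusted p = 0.0162). The 18 m6A writers, erasers and other readers had 5 higher and 1 lower members, also over the list alone (camera adjusted p = 0.144, and adjusted p = 0.0389, higher, with fry). METTL16, a methyltransferase, rose by 0.55 (SE 0.10, adjusted p = 0.00582), and FTO, a demethylase, fell by 0.46 (SE 0.11, adjusted p = 0.0196). The METTL16 call was lost in limma on log2(FPKM + 1) (adjusted p = 0.0724), and the FTO call without transfection control replicate 2 (adjusted p = 0.0929) and without siYTHDF2 replicate 1 (adjusted p = 0.0627). The 32 deadenylation and mRNA decay genes had 6 lower and no higher members, also over the list alone (camera adjusted p = 0.582). Among them the RNA-binding decay factor ZFP36L2 fell by 0.73 (SE 0.07) and the decapping activator DCP1A fell by 0.74 (SE 0.09).

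The largest fitted changes belonged to genes listed at 0 in a whole group, 11 of the 12 named higher and all 12 named lower genes. NPPB, which encodes the B-type natriuretic peptide, had counts of 0 and 0 in the control and 28 and 26 in the siYTHDF2 libraries, and PDLIM3, an actin-binding protein, counts of 32 and 49 in the control and 0 and 0 with siYTHDF2. MSLNL was the exception, with counts of 0 and 3 in the control and 235 and 266 with siYTHDF2. Among abundant genes, chosen after their values were seen, RGS5, a regulator of G-protein signalling found in pericytes, fell by 2.60 on the log2 scale (SE 0.11, adjusted p = 4.26e-06) and GASK1B rose by 1.61 (SE 0.07, adjusted p = 4.26e-06). CKS1B, MYH11, NPC1, MDM2 and RPSA overlap other genes in the table, and their reads may not be separable from those of their neighbours.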

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

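Alternatives added after seeing the data were limma on log2(FPKM + 1), DESeq2, counts divided by 4 and a mean FPKM of at least 1. Of these, limma on log2(FPKM + 1) was the test that the design had named in advance for a table without counts. The YTHDF2 log2 fold change kept its direction and call in all alternatives, between -1.57 and -1.26. Genes called lower stayed within 1.5 times of 1644 in all alternatives. Genes called higher numbered 1408, but 444 with a pseudocount of 0.1, 444 with a pseudocount of 0.5 and 445 with limma on log2(FPKM + 1), and 791 to 1287 when each library was left out. Left-out libraries gave 5 to 108 terms among higher genes. Those terms, 67 in the reported fit, were 30 and 31 with the 2 pseudocounts. Limma on log2(FPKM + 1) gave 31, and 41 with quantile normalization added to it. The edgeR test gave 110 without a filter, 40 with a mean FPKM of at least 5 and 31 without trend and robust shrinkage. The cause of these shifts in terms was not tested. Quantile normalization of log2(FPKM + 1) raised the limma calls from 445 to 1365 higher and from 1211 to 1454 lower genes. That step was the only difference between these 2 fits. The median log2 fold change was 0.022 with it and -0.042 without. The low number of higher genes in limma thus depended on how the libraries were scaled. Lists past the threshold, 6 higher and 7 lower, were 0 and 0 with an estimated correlation and 3 and 4 with fry. Limma on log2(FPKM + 1) gave 4 higher lists, and 3 with quantile normalization added to it. With fry the p53, MAPK, matrix, lysosome and stroma lists kept their calls, and the m6A and steroidogenesis lists, not called with camera, passed. A preset correlation of 0.01 assumes nearly independent genes. Estimated correlations of the called lists ranged from -0.0358 for p53 targets to 0.910 for ribosomal protein genes. The p53, MAPK and stroma lists lay below the preset and yet lost their calls, so that loss cannot be put down to correlated genes alone. With the replicate number as a block, 1020 genes were higher, 1361 lower and 39 terms were enriched among higher genes; the deviations of the libraries sharing a number had a correlation of -0.0527, and 2 pairs are too few to pair them. Among named genes 1301 comparisons with an alternative kept direction and call and 19 lost the call. These genes were largely picked by small p-values in the same libraries, and genes listed at 0 in a whole group were left out. The count therefore says little about the other genes. BDNF, which was not called, ranged from -0.0714 to 0.00805 on the log2 scale with each library left out, and turned positive without transfection control replicate 2. The mean of the YTHDF2 target list turned to -0.11 with no filter on low values, while its test still passed (adjusted p = 0.0162). Counts near 4 and excess zeros limit what can be said of genes with few counts.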

Other observations

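Actin stress fiber genes were enriched among lower genes, with 20 of 47 lower against 5.21 expected (hypergeometric adjusted p = 9.26e-06). Among them were PALLD at -0.60 and MYLK at -0.53, chosen after their values were seen. Some members were called higher, such as LCP1 at 0.66 and SYNPO at 0.41, chosen in the same way. Stress fiber genes stayed enriched when any library was left out. In the NF-kB and cytokine list, 7 of 26 members were higher and 3 lower (8 and 3 adjusted over the list alone; camera adjusted p = 0.224). VCAM1, an adhesion molecule for leukocytes, fell from 349.6 ± 22.5 to 137 ± 8.84 CPM (SD, n = 2 each), while IL33 rose by 0.89 on the log2 scale (SE 0.10, adjusted p = 0.000316). IL33 and PALLD each overlap another gene in the table, and their reads may not be separable from it. Glycolysis and hypoxia genes had 8 higher and 3 lower of 29 members (8 and 4 over the list alone; camera adjusted p = 0.0843), with LDHA, lactate dehydrogenase A, at 0.61 (SE 0.07) and EGLN3, a prolyl hydroxylase, at -0.72 (SE 0.07).

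Cumulus expansion genes had 5 higher and 2 lower of 15, also over the list alone (camera adjusted p = 0.336), with PTGS2, the prostaglandin synthase of ovulation, at 0.85 (SE 0.15). TGF-beta and BMP genes had 3 higher and 8 lower of 34 (3 and 9 over the list alone; camera adjusted p = 0.189), with TGFBR2 at 0.59 (SE 0.08) and SMAD3 at -0.53 (SE 0.07). Cholesterol genes had 1 higher and 3 lower of 23 (camera adjusted p = 0.161), interferon-stimulated genes 2 and 3 of 40 (0.932) and Hippo genes 3 and 2 of 22 (0.820), with the same counts adjusted over the list alone. Immediate early genes had 5 higher and 3 lower of 22 (7 and 4 over the list alone; camera adjusted p = 0.582) and apoptosis regulators 4 and 1 of 27 (3 and 1 over the list alone; camera adjusted p = 0.189). The median, mean and test of a list differed in sign for mRNA decay, G1 and S phase, inhibitor, neurotrophin, granulosa, immediate early, interferon and Hippo genes, none of which passed.

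The tests on zeros, on single libraries and on stroma markers below were chosen after the result was seen; the test on gene length was not. Fitted changes were largest for genes listed at 0 in both libraries of a group. Zeros left by the counting step in any library would fall within a group in 33% of genes at 0 in exactly 2 libraries. Of 123 such genes with 10 or more counts in the other 2, the zeros of 63 lay in 1 group, which is 51.2% (exact 95% interval 42.0 to 60.3). The interval takes genes as independent draws, which was not tested, and does not measure the spread between libraries. Under that assumption the share argues against chance zeros as the whole cause. Still, 41 such genes are expected from arrangement alone, so no single gene of this kind is secured by its call. A candidate explanation for the excess is a change with siYTHDF2, which these libraries test only as a group difference.

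The ribosomal protein rise may reflect either the knockdown or a shift of single libraries. A length trend was present (Spearman's rho -0.126 across 12083 genes, which are not independent), yet after its removal the list mean was 0.25 (SE over genes 0.02), against 0.32 before. In these 4 libraries the fitted trend thus took away only part of the list mean, which argues against length alone as the whole cause there. The genes of this list had an estimated between-gene correlation of 0.91, so the SE over genes does not measure the spread between libraries. The group difference of 0.31 was 1.12 times the largest difference between replicates of a group (0.28), so a shift of single libraries and the knockdown cannot be told apart with 2 libraries per group.

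A smaller share of stromal cells in the siYTHDF2 libraries would lower stroma markers alike, if all marked 1 cell type and no other cells expressed them. Instead 13 of 15 markers lay more than 2 standard errors from the list median of -0.50, 6 above and 7 below it, and DES was called higher. TAGLN, chosen after its values were seen, was not called at 3005 against 3162 CPM, while COL3A1 fell by 1.82 on the log2 scale. The markers thus did not change by 1 common factor. The test cannot decide on cell share, because the list mixes markers of several cell types. The standard errors are also those of each gene's own fit, so small differences between markers exceed them. Markers that granulosa cells also express would fall less. A change of these genes with YTHDF2 interference stays open as untested.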
